A study of Escherichia coli with 8 samples.

How the data were processed

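RNA from Escherichia coli was measured on 8 arrays, 2 in each of 4 groups. Per the labels, the RNA was total RNA from logarithmic-phase cells of the hosts MG1655 and DH5alpha, each with and without the F plasmid. MG1655 is a K-12 strain often used as the wild-type reference, and DH5alpha is a K-12 derivative made for cloning. The labels number the arrays of a group but do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The arrays carry no read depth, and their number limits the precision.

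The deposited table holds 1 intensity per probe set and array on a linear scale, as its values show. The algorithm that made these intensities is not given in the sources used here. The 2% trimmed means of the 8 arrays were 500.3 to 500.4 and differed by at most 0.016%, so the deposited intensities had already been scaled to 1 common level and were used without further scaling. Array medians ran from 104.2 to 144.2, and the highest value of an array from 40948.7 to 178686.9. The table had 7312 probe sets: 4345 for chromosomal genes, 2886 for intergenic stretches, 59 for phages and plasmids and 22 controls. The tests used chromosomal genes, with 1 probe set per gene (the one with the highest mean where several shared a gene), which left 4339 genes. Of the chromosomal probe sets, 4181 were named by their locus tag through the RefSeq gene table of assembly ASM584v2 and 13 through the array's probe table, and 143 kept their own identifier. In the probe table, 4083 chromosomal probe sets were listed with 1 gene and 8 with several, which were left unnamed, and 254 were not listed. Probe sets marked as shared between similar sequences (126 of the genes tested, among them the insertion sequences and ychH) cannot tell copies apart. Of 6 genes with 2 probe sets each, exbD, guaC, insZ and yaiX had probe sets at clearly different levels, exoD and prpB at like levels. No coordinates are given because the build behind the array is not given in the sources used here; the gene order is that of the locus tags.

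Values were tested as log2(intensity + 10.2), the offset being the 10th percentile of all positive values, so a log2 change understates the change of dim genes. One limma model of 4 group means was fitted to all 8 arrays (lmFit, then eBayes with a variance trend; 4 residual and 8.4 prior degrees of freedom), and a second model without interaction gave the effect of F over both hosts and the host difference over both F states. P-values were adjusted by the Benjamini-Hochberg method over the 4339 genes, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors, and errors of group means are standard deviations of 2 arrays. The F plasmid probe sets were tested in the same way among all 7312 probe sets. The design, the alternatives, the rule for named genes and 35 gene lists were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists within a comparison, and again with an estimated correlation. With the estimated correlation, 1 of the 70 list calls held, that of the flagellar list between hosts over both F states. Medians of lists are given relative to the median of all genes, because that median moved with the scaling: with F it was 0.10 on the log2 scale in MG1655 and 0.18 in DH5alpha on the deposited scale, and -0.01 and 0.04 after quantile normalization.

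The text names genes by this rule: in each comparison, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups (no such condition for the interaction), filled up to 10 genes by the smallest p where fewer passed; up to 4 members of each list that passed camera or had 2 called members; and 14 genes that check the host labels. Outside the rule stand cynX and ykgE of the argF-lac region, the genes marked so in the text, and genes named only in the closing section. A log2 change from or to a level that the M13 and P1 probe sets reach (114.6 at most) depends on the offset and is best read from the levels. The fit was tested on simulated data with 200 of 4339 genes changed. For the effect of F it recovered 27.3% of 2-fold and 80.1% of 4-fold changes in MG1655, and 24.6% and 82.2% in DH5alpha. For the interaction it recovered 7.46% of 2-fold and 48.1% of 4-fold changes. The simulated list shift was found in 10 of 10 runs. Genes were simulated as independent of each other, so this does not test camera on lists whose genes vary together.

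Alternatives were other offsets, quantile normalization, median centring, a filter on low values, all probe sets together, other variance models, a 2-fold threshold, the 4 compared arrays alone, the replicate number as a block, and leaving out each array. Others were added after the data were seen: leaving out both arrays that stand apart, array quality weights, a crossed pairing, camera repeated after quantile normalization and without those arrays, and lambda probe sets as background for the argF-lac region. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Control and intergenic probe sets were left out of the tests of genes.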

Results

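The F plasmid is a conjugative plasmid that encodes its own transfer between cells. The series asked which chromosomal genes of Escherichia coli change in expression when the plasmid is present. Its 4 groups cross 2 hosts with the presence of F, with 2 arrays each, labelled MG1655, MG1655F, DH5alpha and DH5alphaF. A pair of probe set kinds checks these labels, those of the F plasmid itself and those of the chromosomal argF-lac region, and they are given first. The first principal component of the 4339 genes held 46.6% of the variance and separated the host labels. MG1655 replicate 1 and DH5alphaF replicate 1 stood apart in their spread of intensities, with highest values of 172889.1 and 178686.9. Replicate arrays correlated across genes at 0.949 in MG1655, 0.963 in MG1655F, 0.973 in DH5alpha and 0.944 in DH5alphaF.

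The probe sets of the F plasmid read high wherever the labels name F. All 10 were higher on each array labelled with F than on any array without it. They read 181.1 to 3574 with F and 4.1 to 382.9 without, and were called in both hosts by limma, with the highest adjusted p at 0.048. The probe set of traD, the coupling protein of conjugation, read 2106 ± 1036 in MG1655F and 12.5 ± 5.94 in MG1655 (SD, n = 2 each). It read 1577 ± 399 in DH5alphaF and 12.35 ± 4.6 in DH5alpha. That of traI, the relaxase that nicks F for transfer, read 3552 ± 30.8 with F and 307.1 ± 107 without it in MG1655, and 2893 ± 15 and 187.1 ± 10.7 in DH5alpha. No F probe set was called for a different response between hosts. The lowest adjusted p was 0.22, for a probe set with a difference of -1.59 ± 0.47, and the design finds few differences of this size. The M13 and P1 probe sets, for sequences no label names, had a median of 18.2 and a highest value of 114.6. The lambda probe sets, likewise named by no label, had a median of 43.25 and a highest value of 475.2, above the level of some F probe sets with F.

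**Figure D1:**
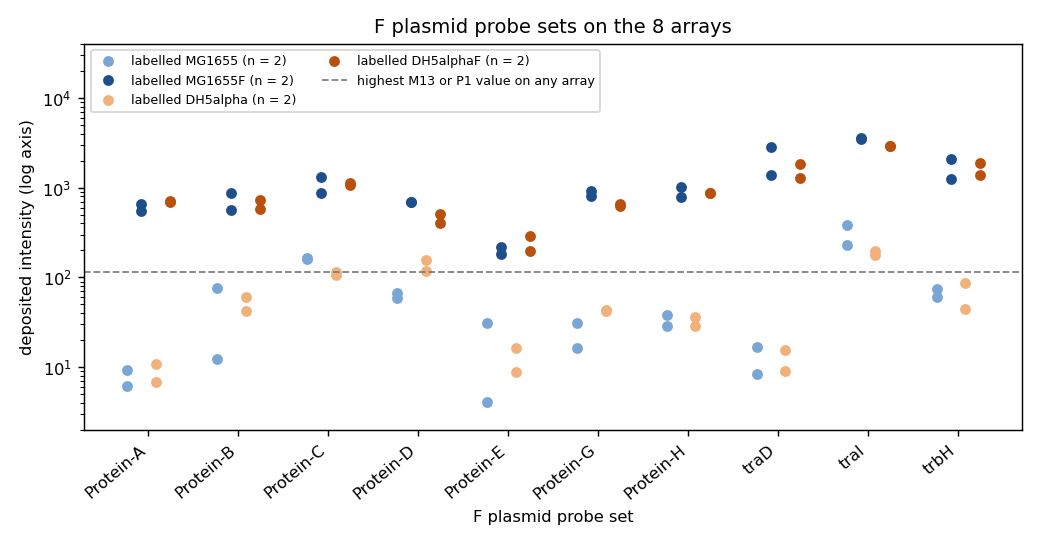
Deposited intensity (log axis) of the 10 F plasmid probe sets on each of the 8 arrays; each point is 1 array, and the dashed line is the highest M13 or P1 value, 114.6. For each probe set the 4 arrays labelled with F lie above the 4 arrays without it.

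Some genes of the argF-lac region went against the host labels. DH5alpha is described as lacking this chromosomal region and as carrying a partial lac copy on a prophage, so the lac genes do not decide the labels. The lac operon, which encodes lactose uptake and cleavage, read lower on the arrays labelled DH5alpha. Without F, lacZ (beta-galactosidase) read 315.3 ± 26.3 on them and 8668 ± 57.9 on the arrays labelled MG1655 (SD, n = 2 each), lower by -4.74 ± 0.26 on the log2 scale (limma adjusted p = 9.5e-08). The genes lacY (lactose permease, 82.7 ± 39.6 and 3292 ± 512) and lacA (transacetylase, 28 ± 10.9 and 1190 ± 175) were lower too, down to levels the M13 and P1 probe sets reach. The repressor gene lacI read 267.2 ± 2.19 and 352 ± 73.9 and was not called (adjusted p = 0.67). Of the 64 genes of the region outside the lac operon, 17 were higher and 1, cynX, was lower on the arrays labelled DH5alpha over both F states, with a median change of 0.71. The others were not called. The higher ones included codA (cytosine deaminase, 772.4 ± 37.2 and 51 ± 51.3 without F, adjusted p = 0.00044) and yagN (336.8 ± 55.3 and 4.85 ± 1.34, adjusted p = 5.2e-05). The list of the whole region, lac operon included, was higher on the arrays labelled DH5alpha without F (camera adjusted p = 1.5e-05, with 10 members higher and 3 lower, and 13 and 3 adjusted over the list alone; adjusted p = 0.56 with an estimated correlation). The genes argF (ornithine carbamoyltransferase, 0.01 ± 0.59), betA (choline dehydrogenase, 1.45 ± 0.46), prpB (methylisocitrate lyase, -0.09 ± 0.44) and cynS (cyanase, 0.82 ± 0.57), also in the region, were not called without F. Over both F states betA was among the 17 higher genes. Because part of the region goes against the host labels, hosts are named below only as the arrays are labelled.

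**Figure D2:**
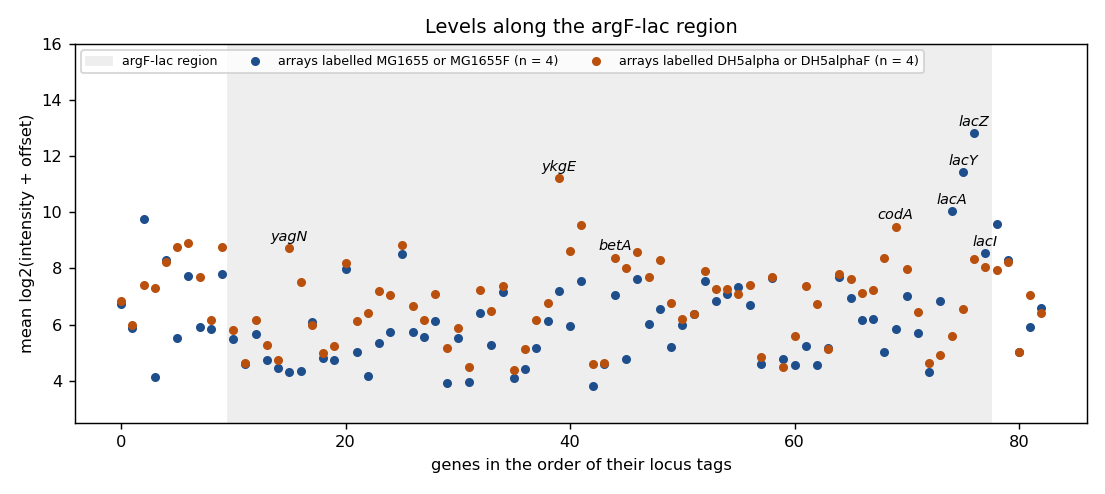
Mean log2(intensity + offset) of each gene along the argF-lac region (grey) and its flanks, in the order of locus tags, for the 4 arrays labelled MG1655 or MG1655F and the 4 labelled DH5alpha or DH5alphaF. The genes lacZ, lacY and lacA lie higher on the arrays labelled MG1655, and yagN, ykgE and codA higher on those labelled DH5alpha.

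In the host labelled MG1655, arnB, arnC and arnA, which act in the addition of aminoarabinose to lipid A, rose with F, and mglA, a transporter gene for galactose, fell. The aminotransferase gene arnB rose from 21.4 ± 2.69, no higher than the M13 and P1 probe sets reach, to 635.3 ± 52.6 (SD, n = 2 each; limma adjusted p = 0.0065). Its log2 change, 4.35 ± 0.51, therefore depends on the offset and ran from 3.59 to 4.83 over the alternatives. In the same operon arnC rose by 2.26 ± 0.43, from 101.4 ± 6.58 to 527.3 ± 82.6, and arnA by 2.18 ± 0.39. The adjacent gene ais rose from 6.65 ± 0.212 to 110.2 ± 20.1. The levels of arnC and ais without F were also no higher than the M13 and P1 probe sets reach, as was the mean of ais with F. The gene puuC, an aldehyde dehydrogenase of putrescine breakdown, rose from 29.9 ± 10 to 344.1 ± 78.9, and glcB, malate synthase G, by 1.78 ± 0.26. The lysozyme inhibitor gene ivy rose by 1.95 ± 0.34, from 1010 ± 524 to 3659 ± 160 (adjusted p = 0.031). The gene flxA rose from 13.35 ± 0.0707 to 91.5 ± 48.8. Both means of flxA are no higher than the M13 and P1 probe sets reach, and its MG1655F arrays read 126 and 57. Among the falls, mglA, the ATPase of the galactose transporter, changed by -1.70 ± 0.22, from 3907 ± 285 to 1197 ± 23.9 (adjusted p = 0.0096). The hexose phosphate transporter gene uhpT fell from 520.7 ± 37.8 to 103.2 ± 2.62. The propionate kinase gene tdcD changed by -2.07 ± 0.37 and the alpha-galactosidase gene melA by -1.48 ± 0.22. The arginine decarboxylase gene speA changed by -1.51 ± 0.28 and yihM fell from 302.9 ± 16.1 to 52.6 ± 3.68. Of 20 alternatives, yihM kept its call in 6, against 18 for arnB. The genes flxA, malM and malK, the last 2 named below, kept theirs in 6, 6 and 7 of 21. The sign of each held in all alternatives.

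In all, 30 of 4339 genes were called in this host, 21 higher and 9 lower with F. The list of carbon source uptake and catabolism fell (camera adjusted p = 1.3e-08; adjusted p = 0.38 with an estimated correlation), with a median of -0.40 relative to all genes. Over all genes 4 of its 65 members fell, mglA, mglC, malK and malM, and 1, the glucose transporter gene ptsG (outside the naming rule here), rose by 1.44 ± 0.22; adjusted over the list alone, 14 fell and 1 rose. The heat shock list rose (adjusted p = 2.1e-06; adjusted p = 0.27 with an estimated correlation; median 0.64), with 0 of 20 members called by limma over all genes and 10 adjusted over the list alone; 439 genes of any kind had an unadjusted p under 0.05. The chaperone genes dnaK and dnaJ had changes of 1.22 ± 0.28 (adjusted p = 0.066) and 1.04 ± 0.26 (adjusted p = 0.11), and the protease gene hslV of 1.08 ± 0.24 (adjusted p = 0.066). Genes of IS2 and IS3, insertion sequences that F also carries, rose as a list (adjusted p = 3.2e-05; adjusted p = 0.27 with an estimated correlation), insE2 by 1.40 ± 0.25 and insF2 by 2.04 ± 0.41 among its 9 members over all genes, and 5 adjusted over the list alone. Their probe sets are shared between copies, so plasmid and chromosomal copies are not told apart.

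Other lists moved in the host labelled MG1655 with 0 called members over all genes (limma). Flagella and chemotaxis fell as a list (camera adjusted p = 1.3e-05, adjusted p = 0.56 with an estimated correlation, median -0.43, 39 of 51 members negative, 0 called adjusted over the list alone). Several members, among them cheZ, flgI, flgL and motB, read within the range of the M13 and P1 probe sets in this host. Members did not all fall: flhD read 346.6 ± 12.4 without and 148.2 ± 1.77 with F. The gene fliC (outside the naming rule here) read 139.3 ± 9.76 and 212.3 ± 42.9. Anaerobic respiration and fermentation fell (4.4e-05; adjusted p = 0.27 with an estimated correlation), with 9 of 40 members adjusted over the list alone, among them the fumarate reductase gene frdB at -1.30 ± 0.28 and the aspartase gene aspA at -1.46 ± 0.35. Ribosomal proteins fell (0.00011; adjusted p = 0.27 with an estimated correlation), which was not called after quantile normalization (0.13). Histidine, tryptophan and branched-chain amino acid synthesis rose (0.0016; adjusted p = 0.56 with an estimated correlation), with all 30 members positive, among them hisH at 0.97 ± 0.34. The TCA cycle (0.027) and the oxidative stress genes of OxyR and SoxRS (0.035) rose, each with adjusted p = 0.27 with an estimated correlation. Citrate synthase, gltA, had a change of 0.96 ± 0.29 and fumarase A, fumA, of -1.19 ± 0.27, neither past the threshold over all genes. Adjusted over the list alone both passed, in opposite directions. Aerobic respiration and ATP synthase fell (0.041; adjusted p = 0.74 with an estimated correlation) and was not called after quantile normalization (0.71). The sigma-S list of stationary phase and general stress did not pass (0.082), although 2 of its members rose: poxB, pyruvate oxidase, by 1.59 ± 0.32 and osmY, a periplasmic osmotic stress protein, by 1.56 ± 0.28. Without both arrays that stand apart, the TCA cycle (0.28) and oxidative stress (0.19) lists lost their calls, the other 8 lists kept theirs, and 3 genes were called by limma. After median centring 1 gene rose and 2 fell, after quantile normalization 7 rose and 6 fell, against 21 and 9, and the count was 1 without a variance trend, 61 with the replicate number as a block and 59 with a crossed pairing. Leaving out MG1655 replicate 1 or 2 left 5 and 8 called genes, and leaving out MG1655F replicate 1 or 2 left 0 in each case by limma, with at least 301 genes at an unadjusted p under 0.05.

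In the host labelled DH5alpha, raiA, bsmA and genes of nitrate reductase rose with F, and xanP fell. The gene raiA, a ribosome hibernation factor, rose by 3.58 ± 0.36 on the log2 scale, from 492.8 ± 208 to 6135 ± 3108 (SD, n = 2 each; limma adjusted p = 0.0011). The biofilm stress gene bsmA rose by 2.66 ± 0.29 and ivy by 2.29 ± 0.34, from 375.2 ± 132 to 1816 ± 18.1 (adjusted p = 0.0088). The asparaginase II gene ansB rose by 2.73 ± 0.51, yniA and ychH by 2.45 ± 0.35 and 2.28 ± 0.44, and bidA from 39.75 ± 22.6 to 301.1 ± 151. The gene glgS, a regulator of surface structures, rose from 43.9 ± 44 to 348.6 ± 85.3 (adjusted p = 0.035). Of the falls, xanP, a xanthine permease gene, changed by -2.29 ± 0.29, from 131.7 ± 7.21 to 18.7 ± 0.283 (adjusted p = 0.0039). Also lower were pth, peptidyl-tRNA hydrolase, which fell by 2.05 on the log2 scale, rsfS, a ribosomal silencing factor, by 1.79, rsuA, a 16S rRNA pseudouridine synthase, by 1.80, and the ribosomal protein genes rpmH and rpsU by 1.61 and 1.22. The size for pth is loose: its DH5alphaF arrays read 86.9 and 287.2, and its change ran from -2.86 to -1.25 over the alternatives. The DNA polymerase III subunit gene holD changed by -1.76 ± 0.37, and ydhI, yeiR, yrdD, b1017 and yrbG fell to levels between 17.75 and 187.8. The size for yrdD is loose too, with DH5alphaF arrays at 90.4 and 285.2. Over 21 alternatives, yrdD kept its call in 8, b1017 in 9 and yrbG in 10, against 20 for raiA. The gene bidA kept its call in 6 of 20. The sign of each held in all alternatives.

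In all, 49 genes were called in this host, 25 higher and 24 lower with F. Anaerobic respiration and fermentation rose (camera adjusted p = 8.4e-08; adjusted p = 0.57 with an estimated correlation), with a median of 0.45 relative to all genes and 37 of 40 members positive. Over all genes 6 members rose, ansB, the nitrate reductase genes narG (by 2.37 ± 0.46), narH (outside the naming rule) and narJ (by 2.27 ± 0.42), the nitrate and nitrite antiporter gene narK (by 2.28 ± 0.44) and the nitrite reductase gene nirB (outside the naming rule); 11 did so adjusted over the list alone. Flagella and chemotaxis fell (adjusted p = 2.6e-13; adjusted p = 0.68 with an estimated correlation), with a median of -0.69 and 50 of 51 members negative. Over all genes 2 of them fell, flhD, the master regulator of flagellar genes, by 1.39 on the log2 scale (adjusted p = 0.042), and fliO, an export apparatus gene, by 1.14; 11 fell adjusted over the list alone. The IS2 and IS3 list did not pass on the deposited scale (0.059; adjusted p = 0.68 with an estimated correlation), although insE2 and insF4 rose by 1.78 ± 0.25 and 1.41 ± 0.30. It did after quantile normalization (0.039) and without both arrays that stand apart (0.0018). Iron uptake, with a median of -0.32, had the same adjusted p (0.059; adjusted p = 0.93 with an estimated correlation), and 0.03 and 0.041 under these alternatives. Ribosomal proteins did not pass (0.16), although rpmH and rpsU fell; the list's median was 0.15 relative to all genes and -0.12 after quantile normalization. No other list had an adjusted p under 0.059 on the deposited scale. Carbon source uptake had 0.12, and 0.039 after quantile normalization. DH5alphaF replicate 1 stands apart in this host, and without it and MG1655 replicate 1 the count was 18, the flagellar list had an adjusted p of 9.5e-05 and the anaerobic list of 9.2e-10. After median centring 5 genes rose and 9 fell, after quantile normalization 11 rose and 16 fell, against 25 and 24, and the count was 81 with a crossed pairing and 0 by limma without a variance trend (598 at an unadjusted p under 0.05). Without DH5alpha replicate 1 or 2, DH5alphaF replicate 1, or MG1655F replicate 1 or 2, the count was 4, 8, 5, 23 and 23.

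The calls in the hosts shared few genes. Of the 21 and 25 genes that rose, 2 were the same, ivy and insE2, against 0.12 if the lists were independent, and none of the genes that fell. The probe set of insE2 does not tell the chromosomal copies from the element on F, which leaves ivy. The simulated fit recovered only 27.3% of 2-fold changes in MG1655 and 24.6% in DH5alpha, so few shared calls do not show unlike responses. Across the 4339 genes, which are not independent replicates, the effects of F in both hosts had a Pearson correlation of 0.05 and a Spearman correlation of 0.04, while the host difference with and without F correlated at 0.63. Over both hosts together, 13 genes were called, 9 higher and 4 lower. The gene ivy rose by 2.12 ± 0.25 and insE2 by 1.59 ± 0.20 (limma adjusted p = 0.0041 for each). Also higher were arnB (3.11 ± 0.49), ymgD (1.96 ± 0.32), arnA (1.72 ± 0.30), insF4 (1.39 ± 0.22), ptsG (1.06 ± 0.20) and the sigma-S genes osmB (1.47 ± 0.28) and osmY (1.29 ± 0.22). The genes yihM (-2.02 ± 0.33), ydiY (-1.37 ± 0.25), flhD (-1.28 ± 0.21) and plaP, a putrescine importer (-1.15 ± 0.22), fell. Some of these calls were fragile: ptsG, plaP, osmB and ydiY each had a limma adjusted p of 0.048. Of 20 alternatives, ptsG kept its call in 1, plaP in 4, osmB in 5 and ydiY in 6, against 19 for ivy. Their sign held in all 20. Levels of arnB, ymgD and yihM in some groups lie in the range of the M13 and P1 probe sets, so their values depend on the offset.

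**Figure D3:**
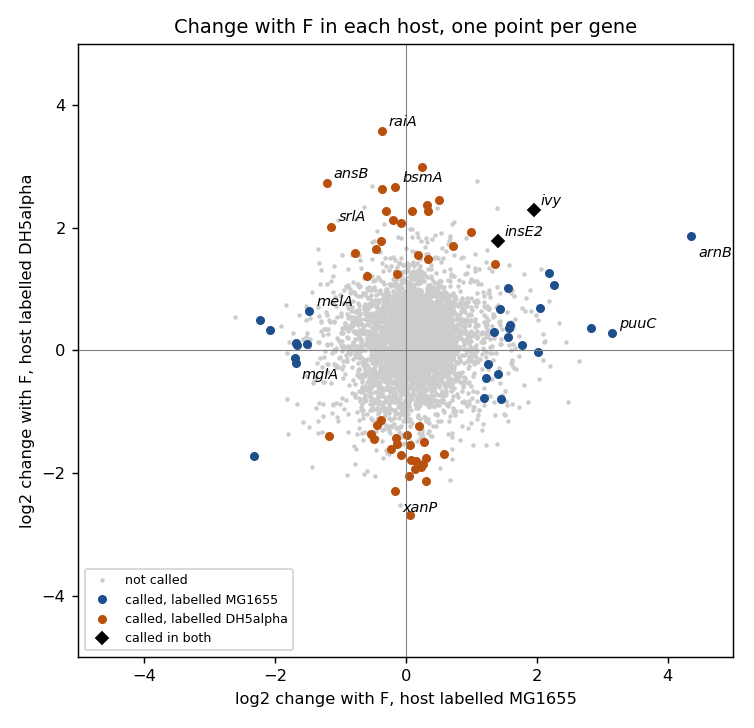
Log2 change with F in the host labelled MG1655 (horizontal) and in the host labelled DH5alpha (vertical), 1 point per gene for 4339 genes. Called genes lie mostly along 1 axis or the other, with insE2 and ivy called in both hosts.

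Over both hosts the flagellar list fell (camera adjusted p = 1.8e-17; adjusted p = 0.38 with an estimated correlation), with a median of -0.57 relative to all genes, 48 of 51 members negative, 1 called over all genes (flhD) and 8 adjusted over the list alone. The IS2 and IS3 list rose (3.4e-05; adjusted p = 0.15 with an estimated correlation), with 2 of 9 members over all genes and 6 adjusted over the list alone. The sigma-S list rose (0.019; adjusted p = 0.38 with an estimated correlation), with 2 of 29 members and 4 adjusted over the list alone. Purine and pyrimidine synthesis fell (0.017; adjusted p = 0.63 with an estimated correlation) and histidine, tryptophan and branched-chain synthesis rose (0.024; adjusted p = 0.88 with an estimated correlation), both with 0 called members by limma. The purine list was not called after quantile normalization (0.076), nor the sigma-S list without both arrays that stand apart (0.19). The following lists, not called on the deposited scale, were called after quantile normalization: heat shock (0.13, then 0.01), TCA cycle (0.076, then 0.0034) and ribosomal proteins (0.36, then 0.042). The lists of the SOS response, the Cpx regulon, sigma-E and phage shock, colanic acid, curli, and the nucleoid proteins and regulators of F transfer had adjusted p-values of 0.65, 0.36, 0.84, 0.96, 0.21 and 0.99 over both hosts and were not called in either host. After quantile normalization 2 genes rose and 1 fell, after median centring 1 rose and 1 fell, against 9 and 4, and the count was 1 without a variance trend. Without MG1655 replicate 2, MG1655F replicate 1 or 2, DH5alpha replicate 2, or DH5alphaF replicate 1 or 2, the count was 5, 2, 2, 2, 6 and 4.

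**Figure D4:**
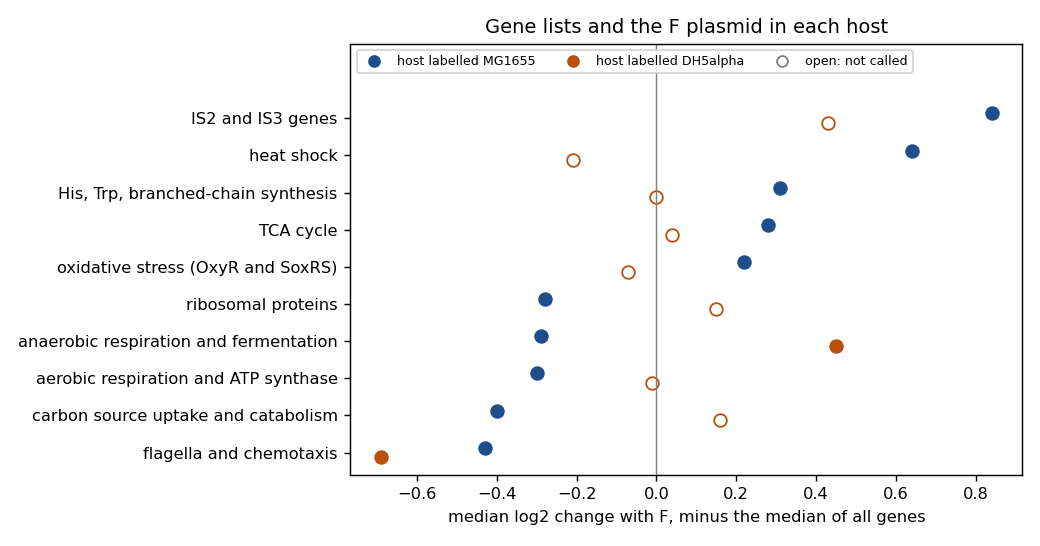
Median log2 change with F of each gene list called in at least 1 host, relative to the median of all genes; filled points passed camera in the host labelled MG1655 (blue) or DH5alpha (orange). Flagella lie to the left in both hosts and anaerobic respiration on opposite sides; in the host labelled DH5alpha the sign of the ribosomal (0.15, then -0.12), oxidative stress (-0.07, then 0.04) and aerobic (-0.01, then 0.03) lists turned with quantile normalization.

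The change with F differed between the hosts for 4 genes. Samples with and without F may also differ in growth, which cannot be told apart from an effect of F here. The differences, the effect in DH5alpha minus that in MG1655 as labelled, were 3.95 ± 0.50 on the log2 scale for raiA (limma adjusted p = 0.0079), 3.17 ± 0.36 for srlA (0.0052), 2.82 ± 0.41 for bsmA (0.018) and 2.13 ± 0.31 for melA (0.018). The sorbitol transporter gene srlA read 1124 ± 21.8 without and 503.3 ± 30.7 with F in MG1655, and 718.4 ± 199 and 2919 ± 553 in DH5alpha (SD, n = 2 each). The gene melA read 11562 ± 1575 and 4138 ± 698 in MG1655, and 403.2 ± 16 and 635.2 ± 18.3 in DH5alpha. The next 6 genes by p were ansB (3.94 ± 0.72), uhpT (2.71 ± 0.49), puuA (-2.53 ± 0.44), ybjX (-2.25 ± 0.41), glcD (-1.97 ± 0.34) and hscB (-1.78 ± 0.32), each with an adjusted p of 0.054 and not called. The list of anaerobic respiration and fermentation responded more positively in DH5alpha (camera adjusted p = 5.4e-13; adjusted p = 0.22 with an estimated correlation), with a median difference of 1.11 relative to all genes, 0 of 40 members called by limma over all genes (490 genes had an unadjusted p under 0.05) and 17 adjusted over the list alone. So did carbon source uptake and catabolism (3.4e-08; adjusted p = 0.74 with an estimated correlation; median 0.57), with 1 member, srlA, over all genes and 16 higher and 1 lower adjusted over the list alone. Heat shock responded more negatively (2.3e-05; adjusted p = 0.47 with an estimated correlation; median -0.65), with 6 members adjusted over the list alone, among them hslV at -1.76 ± 0.34. Ribosomal proteins (5.3e-05; adjusted p = 0.47 with an estimated correlation) had a median difference of 0.55 that was -0.04 after quantile normalization (adjusted p = 0.99). Flagella (0.025; adjusted p = 0.86 with an estimated correlation) had a median of -0.41, with an adjusted p of 0.46 after quantile normalization. Without both arrays that stand apart 1 gene, raiA, was called, and of these 5 lists flagella lost its call (0.82). Quantile normalization called 4 genes higher and 1 lower, median centring 0 by limma (468 at an unadjusted p under 0.05), a filter on low values 18, the replicate number as a block 32, a crossed pairing 44, and a fit without a variance trend 0 by limma (401 at an unadjusted p under 0.05). Without MG1655 replicate 2, MG1655F replicate 1, DH5alpha replicate 1 or 2, or DH5alphaF replicate 2, the count was 14, 0, 2, 16 and 14, with 352 genes at an unadjusted p under 0.05 for the 0.

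Genes of motility differed between the hosts. Without F, all 51 measured genes of flagella and chemotaxis were higher on the arrays labelled DH5alpha (camera adjusted p = 3.7e-89; adjusted p = 0.078 with an estimated correlation), with a median of 4.19 relative to all genes. Flagellin, fliC, read 18914 ± 3225 on them and 139.3 ± 9.76 on those labelled MG1655 (SD, n = 2 each), a log2 difference of 6.97 ± 0.23 (limma adjusted p = 2.5e-09). The chemotaxis genes cheA and tar differed by 5.98 ± 0.28 and 5.75 ± 0.36, and the filament cap gene fliD by 6.75 ± 0.25. The genes cheZ (4287 ± 566 and 14.95 ± 2.76), flgI (3122 ± 854 and 18.2 ± 6.08), flgL (2292 ± 368 and 23.15 ± 10.8), motB (2782 ± 145 and 36.8 ± 17.4) and flxA (1546 ± 224 and 13.35 ± 0.0707) read within the range of the M13 and P1 probe sets on the arrays labelled MG1655. The porin gene nmpC read 10448 ± 1745 and 6.55 ± 6.43, the latter also in that range, so its log2 difference, 8.01 to 10.75 over the alternatives, depends on the offset. The galactitol genes gatB (by 3.94 ± 0.22), gatC (2963 ± 572 and 97.55 ± 44.9) and gatD (965.7 ± 354 and 12.35 ± 2.9) were also higher, the low levels of gatC and gatD again in that range, as were the glyoxylate shunt genes aceA (2.94 ± 0.37) and aceB (2.89 ± 0.21). Lower on the arrays labelled DH5alpha were kduD (21.05 ± 1.63 and 7222 ± 47.6) and kdgT (19.7 ± 2.83 and 4389 ± 286) of pectin breakdown, down to that range, and kduI (-6.18 ± 0.30), melA (-4.80 ± 0.22) and xanP (-4.59 ± 0.29). The purine genes purT (-4.05 ± 0.27) and purH (-3.74 ± 0.23) were lower too, as were asnC, a regulator of asparagine synthesis (-3.99 ± 0.42), and the ribokinase gene rbsK (-2.75 ± 0.25). The directions in this comparison and the next rest on host labels that part of the argF-lac region goes against.

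Without F, 249 genes differed between the hosts, 119 higher and 130 lower on the arrays labelled DH5alpha. Purine and pyrimidine synthesis was lower (camera adjusted p = 0.00074; adjusted p = 0.56 with an estimated correlation), with 13 of 29 members lower and 4 higher, among them codA and codB, and 14 and 4 adjusted over the list alone. The sigma-S list was lower (1.7e-06; adjusted p = 0.12 with an estimated correlation), with 3 of 29 members and 7 adjusted over the list alone; the acid stress chaperone genes hdeB and hdeA read 76.2 ± 0.849 and 694.5 ± 63.4, and 155.7 ± 10.7 and 1180 ± 269. The lac operon (1.7e-06; adjusted p = 0.12 with an estimated correlation, 3 of 4 members) and acid resistance (0.00016; adjusted p = 0.52 with an estimated correlation, 2 of 13, and 6 adjusted over the list alone) were lower. Carbon source uptake was lower (0.0093; adjusted p = 0.64 with an estimated correlation), with 11 of 65 members lower and 4 higher, and 16 and 6 adjusted over the list alone. Iron uptake was lower (0.005; adjusted p = 0.56 with an estimated correlation), with 2 of 32 members, among them the siderophore receptor gene cirA (-1.41 ± 0.32), and 3 adjusted over the list alone. Type 1 fimbriae were lower (0.0096; adjusted p = 0.56 with an estimated correlation), with 2 of 9 members, among them the main subunit gene fimA (-1.31 ± 0.28), and 5 adjusted over the list alone. Phosphate starvation was lower (0.043; adjusted p = 0.64 with an estimated correlation), with 1 of 30 members, the phosphate-binding protein gene pstS (-1.49 ± 0.27), and was not called without both arrays that stand apart (0.1). The DLP12 prophage list was higher (0.035; adjusted p = 0.64 with an estimated correlation), with 2 of 23 members, nmpC and borD (2.01 ± 0.34), and 4 adjusted over the list alone. After quantile normalization its adjusted p was 0.068. Ribosomal proteins were lower (0.026; adjusted p = 0.56 with an estimated correlation; median -0.21), and the sign turned after quantile normalization (median 0.12, adjusted p = 0.79). The small heat shock chaperone genes ibpB and ibpA differed by -2.38 ± 0.36 and -1.46 ± 0.38, while the heat shock list had an adjusted p of 0.96. The genes recA, relA, endA, gyrA and deoR, named in advance because DH5alpha is described as mutated in them, differed by -0.16 to 0.14 and were not called. Of the list of genes mutated in DH5alpha, hsdR (a restriction enzyme subunit, outside the naming rule) was called, at 326.5 ± 88 on the arrays labelled DH5alpha and 16.05 ± 8.13 on those labelled MG1655. With F recA was called too, at 1910 ± 400 and 755.4 ± 38.4. A probe outside a small lesion does not check the lesion. After median centring 126 genes were higher and 89 lower, against 119 and 130.

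With F, 526 genes differed between the hosts, 229 higher and 297 lower, and 182 of them also differed in the same direction without F, against 15.2 if the lists were independent. Anaerobic respiration and fermentation was higher on the arrays labelled DH5alphaF, with 22 of 40 members (camera adjusted p = 1.1e-12; adjusted p = 0.12 with an estimated correlation) and 27 adjusted over the list alone, while without F its adjusted p was 0.64. Iron uptake was lower, with 9 of 32 members (2.5e-06; adjusted p = 0.18 with an estimated correlation) and 17 adjusted over the list alone, and heat shock was lower, with 6 of 20 members (1.3e-05; adjusted p = 0.20 with an estimated correlation) and 11 adjusted over the list alone. Carbon source uptake, lower without F, was higher with F (0.0056; adjusted p = 0.42 with an estimated correlation), with 15 of 65 members higher and 7 lower, and 18 and 7 adjusted over the list alone. Over both F states its adjusted p was 0.83. The genes nirB and narG, outside the naming rule here, belong to the first list: nirB read 517.4 ± 27.4 in DH5alphaF and 59 ± 19.4 in MG1655F (SD, n = 2 each), and narG 1102 ± 0.283 and 90.7 ± 11. Over both F states 426 genes differed, 183 higher and 243 lower on the arrays labelled DH5alpha, and the flagellar list, with 51 of 51 members higher, held with an estimated correlation (adjusted p = 3.5e-88; adjusted p = 0.031 with an estimated correlation). After median centring these were 195 higher and 168 lower. With F, leaving out MG1655F replicate 1 or 2 or DH5alphaF replicate 1 gave 239 and 257 called genes, and 159 higher and 186 lower ones, in that order, and a fit without a variance trend gave 303.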

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

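The tests of explanations below were chosen only after the results were seen, except that of array noise and the splits of the arrays. The limma and camera calls on the deposited scale quoted beside them belong to the design fixed before the data were examined.

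The change with F differed between the hosts, with log2 differences of 3.95 for raiA, 3.17 for srlA, 2.82 for bsmA and 2.13 for melA. A growth difference between the samples with and without F was not tested for these genes. Unequal spread of intensities on MG1655 replicate 1 and DH5alphaF replicate 1 could make such differences, but the smallest share of a difference kept under quantile normalization or without these arrays was 0.89. Without them srlA, bsmA and melA lost their calls (differences 3.38, 3.20 and 2.24; adjusted p = 0.056, 0.076 and 0.15) though none shrank, with fewer arrays and so less power in the fit; over all alternatives their adjusted p ran from 0.00058 to 0.17, 0.0066 to 0.17 and 0.015 to 0.21. Beyond these 4 genes, array noise may hide a shared response across all genes: F effects from single arrays correlated at 0.07 to 0.33 within a host and at -0.18 to 0.28 between hosts, and though the means differ by 0.18 the ranges overlap, so noise cannot be told apart from unlike responses there. Of 34 splits of the arrays, 1 gave as many genes as the real one for F over both hosts (13, highest other 1) and 1 for the host (426, highest other 0), the real one itself. For the host, every other split leaves the large host difference in the residual, so few calls were bound to follow. For F, many other splits are unequal between the hosts and so overlap with the host term. Neither comparison therefore decides whether chance made the calls.

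Of 64 genes of the argF-lac region outside the lac operon, 17 were higher on the arrays labelled DH5alpha. The host names may be exchanged: on each of these arrays at least 42.2% of the region's genes read above every M13 and P1 probe set, and up to 37.5% on the arrays labelled MG1655 (7.81% to 20.3%, and 1.56% to 3.12%, with lambda probe sets added), but this largely restates the difference, so an exchange cannot be told apart from other causes. Hybridization to sequence both hosts share could set the level of the genes that read alike. As only 28.1% differed, against 9.82% of all genes, it cannot be told apart from other causes for the region as a whole either. Shared sequence expressed alike in both hosts would give like levels, so the 17 higher genes and 1 lower gene argue against it there. The region may be present but silent on the arrays labelled MG1655: 0 of 4276 windows of as many genes read lower, yet the region's median there, 5.67 on the log2 scale, lay above that of the M13 and P1 probe sets, 4.69, so silence and absence cannot be told apart. Silence on the arrays labelled MG1655 would not by itself make 17 genes read higher on arrays of a host described as lacking them. The region was dim on the arrays labelled DH5alpha too, where 339 of the windows read lower. Of all genes, 66.6% to 80.3% read above every M13 and P1 probe set of their array. The lambda probe set for gene M read 195.6 to 475.2 over the arrays, so the lambda sets may not measure background. The lac genes, high on the arrays labelled MG1655, decide nothing, since DH5alpha is described as carrying a partial lac copy on a prophage, and an exchange of names would exchange the hosts of both F comparisons too.

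The flagellar list had a negative median with F in both hosts, with 39 of 51 members negative in MG1655, where none was called, and 50 in DH5alpha (camera adjusted p = 1.3e-05 and 2.6e-13, and adjusted p = 0.56 and 0.68 with an estimated correlation). In MG1655 several members read within the range of the M13 and P1 probe sets. Scaling of the arrays could lower the list's median. For F over both hosts, 0.91 of the median fall relative to all genes was kept after quantile normalization. Median centring shifts all genes alike and cannot change this share. The share was not tested in each host, so scaling is not settled there. A later growth phase with F would likely lower ribosomal genes and raise sigma-S genes in both hosts, and the ribosomal median relative to all genes in DH5alpha was 0.15 on the deposited scale, with 44 of 55 members positive, and -0.12 after quantile normalization. In MG1655 it was -0.28 and -0.06, and the sigma-S medians were 0.23 in DH5alpha and 0.11 in MG1655 on the deposited scale, so a growth difference cannot be told apart from an effect of F.

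Before the median of all genes is taken off, the median differences of the F effect between hosts were 1.14 for anaerobic respiration, 0.61 for carbon source uptake, 0.58 for ribosomal proteins, -0.37 for flagella and -0.61 for heat shock. The pBR322 probe sets for bla, tet and g456436 had medians of 28042, 3347 and 495.2 over the arrays, with bla from 21700.5 to 36827.1, and their source is not given in the sources used here. Of 2886 intergenic probe sets, 2 were called with F in MG1655 and 16 in DH5alpha by limma.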

How the results depend on the processing

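The main counts of called genes were 30 for F in the host labelled MG1655, 49 in the host labelled DH5alpha, 4 for the interaction, 13 for F over both hosts and 249, 526 and 426 for the host difference without F, with F and over both. The cause of the movements below was not tested.

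Scaling: after quantile normalization the counts were 13 for F in MG1655, 27 in DH5alpha and 3 over both hosts. After median centring they were 3, 14 and 2, and 0 for the interaction by limma, with 468 genes at an unadjusted p under 0.05. The ribosomal list lost its call and turned direction after quantile normalization for the interaction (camera adjusted p = 0.99) and for the host difference without F (0.79). For F over both hosts it was called lower only after that normalization (0.042, against 0.36).

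Offset, filter and genes: with an offset of 1 the counts were 18 for F in MG1655 and 8 for the interaction. A filter on low values gave 18 for the interaction, and testing all probe sets together gave 22 for F over both hosts. Variance: without a variance trend the counts were 1 for F in MG1655, 1 over both hosts and 303 for the host difference with F. It gave 0 by limma for F in DH5alpha and 0 for the interaction, with 598 and 401 genes at an unadjusted p under 0.05. A fit of only the 4 arrays compared gave 51 for F in MG1655.

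The replicate number as a block gave 61 for F in MG1655 and 32 for the interaction. A crossed pairing, with the MG1655F numbers exchanged and chosen after seeing the data, gave 59 for F in MG1655, 81 in DH5alpha and 44 for the interaction. Without both arrays that stand apart, also chosen after seeing the data, the counts were 3 for F in MG1655, 18 in DH5alpha, 1 for the interaction and 2 over both hosts.

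Leaving out 1 array gave 0 to 31 genes for F in MG1655, with 5 and 8 without MG1655 replicate 1 and 2 and 0 by limma without MG1655F replicate 1 or 2 (at least 301 at an unadjusted p under 0.05). For F in DH5alpha it gave 4 to 70, with 4 and 8 without DH5alpha replicate 1 and 2, 5 without DH5alphaF replicate 1, and 23 without MG1655F replicate 1 or 2. For the interaction it gave 0 to 16, with 0 without MG1655F replicate 1 (352 unadjusted), 2 and 16 without DH5alpha replicate 1 and 2, and 14 without MG1655 replicate 2 or DH5alphaF replicate 2. For F over both hosts it gave 2 to 15, with 2 without MG1655F replicate 1 or 2 or DH5alpha replicate 2, 5 without MG1655 replicate 2, and 6 and 4 without DH5alphaF replicate 1 and 2. For the host difference with F it gave 239 to 540, with 239 and 257 without MG1655F replicate 1 and 2 and 159 higher and 186 lower without DH5alphaF replicate 1. The correlation of the effects of F ran from -0.06 to 0.16.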

Other observations

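The tests of neighbouring genes below were chosen only after the results were seen.

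Between the hosts, differences fell in runs of adjacent genes. On the arrays labelled DH5alpha, 5 adjacent oligopeptide transporter genes from oppA to oppF were higher, with a median of 1.26 on the log2 scale, and 4 genes from garK to garP, for galactarate use, by 1.36. Lower were 7 genes from rbsD, of ribose uptake, to hsrA (median -2.39), 5 genes from glaH to gabP, of glutarate and aminobutyrate use (-1.98), and 4 genes from ygfF to gcvT, of glycine cleavage (-0.97).

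Genes called with F also lay next to each other. In MG1655, 10 of 30 called genes had a called neighbour, among them ais, arnB, arnC and arnA, and in DH5alpha 14 of 49, among them narK, narG, narH and narJ. Random draws gave at most 6 and 8, with a permutation p of 1e-04 for each, the smallest the permutations can give. The other called genes had no called neighbour. Random probe error could scatter calls over the chromosome, which these 10 and 14 genes argue against for part of the calls only. The 10 include insF2 and insE2, whose probe sets do not tell plasmid and chromosomal copies apart. The draws treat genes as independent, while genes of an operon can vary together for reasons other than F. So the draws cannot tell operons responding to F as units from other differences between the samples.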
